A study of Mus musculus with 9 samples.

How the data were processed

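RNA from 9 mouse tumour samples was sequenced, with 3 libraries for each of PBS, Lipo-BiTE and Lipo-TriTE. Per the labels' protocols, tumours were frozen in liquid nitrogen and homogenised in Trizol, DNA was removed on a column and RNA was collected on a second one. Fragmented mRNA was copied with random primers, second strands were made with DNA polymerase I after RNase H treatment, and libraries of short fragments were amplified by PCR. The design text of the series names sorted CD3-positive T cells as the material, and no step of sorting appears in the protocols. Whether the kit kept strand is not stated. A random-primed library without molecular identifiers counts reads, not molecules.

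The deposited values are raw read counts per gene, whole numbers that sum to a different total in each library, per the file headers and the values themselves. They came as one table of 44806 entries with 9 count columns. The aligner, the counting tool and their settings are not given in the sources used here. Gene identifiers in the table name C57BL/6NJ gene models, and the deposited columns of gene length, start and end were used only for positions. The reference annotation at hand was for another assembly and was not used. The count columns carry the word untreated where the labels say PBS; their numbers match the label replicates 1 to 3 of the one group left, so they were taken as the PBS libraries, which is an inference. Of the table's entries 3710 were unnamed assembled loci, which took 1.17% to 2.14% of the counts, and 1135 of them were tested. Names turned into dates numbered 24 and were left as deposited. In all, 52 names occurred more than once, and the entry with the most counts kept the name while the others went under their identifiers.

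Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr, which left 16596, and libraries were scaled by TMM. The main test was the edgeR quasi-likelihood F test with robust estimation over all 9 libraries, with 1 mean per group and no covariate, which gave 6 residual degrees of freedom and a median prior of 4.99. Each of 3 comparisons was a contrast of 2 group means, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with calls at an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Means and SDs are of CPM on TMM-scaled totals. Where a group had no counts, the fold was bounded with 3 counts over the group; where it had 1 to 3, a ratio of counts per library total is given with an exact 95% interval.

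A total of 38 gene lists, 16 of cell type markers and 22 of functions, was fixed before the data were examined, as were the tests, the comparisons, the alternatives and the rule for naming genes. In 35 lists at least 5 members were tested. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Some genes stand in more than one list: 7 of the suppressive myeloid list and 5 of the regulatory T cell list are shared. The mean log2 CPM of each marker list per library was compared by exact two-sided permutation tests, for which 3 against 3 libraries give 10 splits and no p under 0.1.

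Genes were named by 3 rules per comparison: the 10 largest rises and 10 largest falls among called genes that had a mean of at least 1 CPM in the higher group and no overlap between libraries, leaving out predicted models, receptor segments and pseudogenes; up to 4 members of each described list with the smallest p; and the panel Cd3e, Cd4, Cd8a, Gzmb, Prf1, Ifng, Foxp3, Pdcd1, Cd274 and Erbb2 whatever its result. Genes outside these rules are said to be chosen after their values were seen. A gene these rules also picked in Lipo-TriTE against Lipo-BiTE is not reported here.

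The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 34%, 29% and 30% of the 2-fold changes and 83%, 83% and 78% of the 4-fold changes, on 16008, 16035 and 16021 genes for Lipo-BiTE against PBS, Lipo-TriTE against PBS and Lipo-TriTE against Lipo-BiTE, with 2, 3 and 10 false calls. A raised list was called in each comparison and 0 of 20 random lists. Each gene was drawn independently in these simulations. They therefore do not show how camera with a preset correlation behaves on lists whose members are correlated. For the overlap of the comparisons with PBS, 20 sets of all 9 libraries were simulated from the PBS means with no group change. In each set both simulated treatments were compared with the same simulated PBS libraries. No pair of libraries was alike within sampling noise: chi-square per degree of freedom was 4.81 for PBS 2 and 3 and 22.6 to 89.7 for the other pairs within groups.

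Alternatives were DESeq2 1.42.0 size factors, total counts without TMM, no filter, a filter of at least 1 CPM in 3 libraries, a fit of only the 2 groups compared, the replicate number as a block, the DESeq2 Wald test, limma voom with quality weights, an absolute log2 fold change of at least 1, and leaving out each library in turn. Leaving out the unnamed loci, thinning every library to the smallest total and keeping 2 libraries per group were added after the data were seen. With total counts in place of TMM the median log2 change of all genes moved to −0.155 in Lipo-BiTE against PBS and to 0.112 in Lipo-TriTE against Lipo-BiTE.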

Results

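RNA was sequenced from mouse tumours of MB49, a bladder cancer cell line of the mouse, which the labels describe as overexpressing HER2, the receptor tyrosine kinase encoded in the mouse by Erbb2. Whether the added HER2 is of human or mouse sequence is not stated. Only counts of mouse Erbb2 are given here, and they may not include the added HER2. Mice had received PBS, Lipo-BiTE or Lipo-TriTE, and each treatment had 3 libraries. BiTE is the usual short name of a bispecific T cell engager, an antibody-based molecule that ties a T cell to a tumour cell; the labels spell out neither agent's binding targets. The stated purpose was to learn what underlies the response to each treatment. Sources differ on the material: the design text speaks of T cells sorted from tumours by CD3, whereas the sample labels and the extraction protocol describe frozen whole tumour tissue.

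The libraries held from 13152783 to 20273548 counts. PBS 1, 2 and 3 held 13152783, 16419940 and 16163669, Lipo-BiTE 1, 2 and 3 held 14594367, 13971713 and 13693601, and Lipo-TriTE 1, 2 and 3 held 20273548, 15290974 and 15037557. Levels are given as CPM, counts scaled to the effective library total. A total of 3 counts in a library, the floor used here, equalled 0.148 to 0.228 CPM. Intervals and floors cover counting error only. The 20 most abundant genes took 5.03% to 6.4% of the counts. Expression profiles separated the groups on the first principal component, which held 54.3% of the variance. PBS libraries lay between −103.3 and −90.93, Lipo-BiTE libraries at −23.85, 13.33 and 51.15, and Lipo-TriTE libraries between 77.48 and 92. PBS 1 stood apart from the other PBS libraries on the second component, at 58.39 against 0.771 and 1.951. PBS 2 and 3 were also the closest pair within a group, with a Pearson r of log2 CPM of 0.985 against at most 0.974 for other pairs. Whether PBS 2 and 3 share a source is not stated, so the spread among PBS libraries may be understated. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples.

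**Figure D1:**
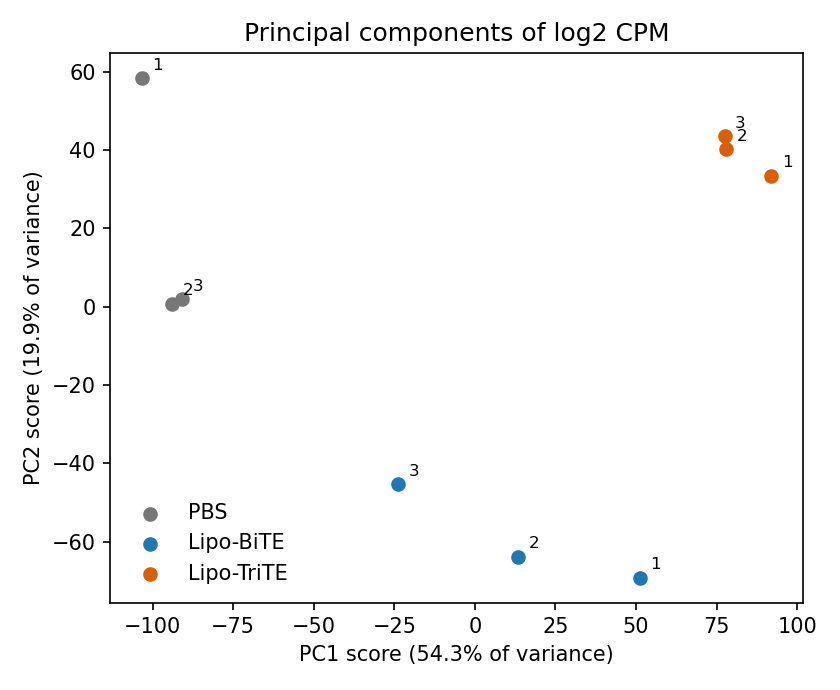
Principal components 1 (54.3% of variance) and 2 (19.9%) of log2 CPM over the tested genes, with one point per library coloured by treatment. PBS, Lipo-BiTE and Lipo-TriTE libraries lie in that order along component 1.

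Transcripts of epithelial and tumour cells were present in every library beside those of T cells. Krt8, a keratin of simple epithelia chosen after its values were seen, lay above Cd3e, a subunit of the T cell receptor complex, in 9 of 9 libraries. The ratio of Krt8 to Cd3e CPM ran from 1.5 to 164, with means of 126 ± 35.3 in PBS, 18 ± 10.6 in Lipo-BiTE and 3.47 ± 1.72 in Lipo-TriTE (SD, n = 3 each). Mean Krt8 was 465 CPM in PBS, 329.1 in Lipo-BiTE and 246.5 in Lipo-TriTE. The mean log2 CPM of the T cell markers was 2.14 in PBS, 4.72 in Lipo-BiTE and 6.67 in Lipo-TriTE. The macrophage and monocyte score stood at 3.5, 6.34 and 6.03, the B cell score at −0.32, 1.22 and 6.37, and the fibroblast score at 5.07, 4.1 and 4.49. Groups did not overlap in 83 of the 105 pairs of a list and a comparison, where chance gives 10%, and the smallest p of the exact two-sided permutation test with 3 against 3 libraries is 0.1. Each change reported is thus one of transcript level in a mixture of cells.

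Of 35 gene lists with at least 5 tested members, the camera test called 23 higher and 3 lower in Lipo-BiTE against PBS, 23 and 3 in Lipo-TriTE against PBS, and 16 and 5 in Lipo-TriTE against Lipo-BiTE. Camera sets a list against all other genes with a preset correlation of 0.01 between members. With an estimated correlation 2, 2 and 0 lists were called. Fry, which tests each list on its own and not against other genes, called 26, 28 and 16. Other splits of the same libraries, which still hold part of the treatment difference, gave up to 25, 23 and 20 camera calls with the preset correlation.

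**Figure D2:**
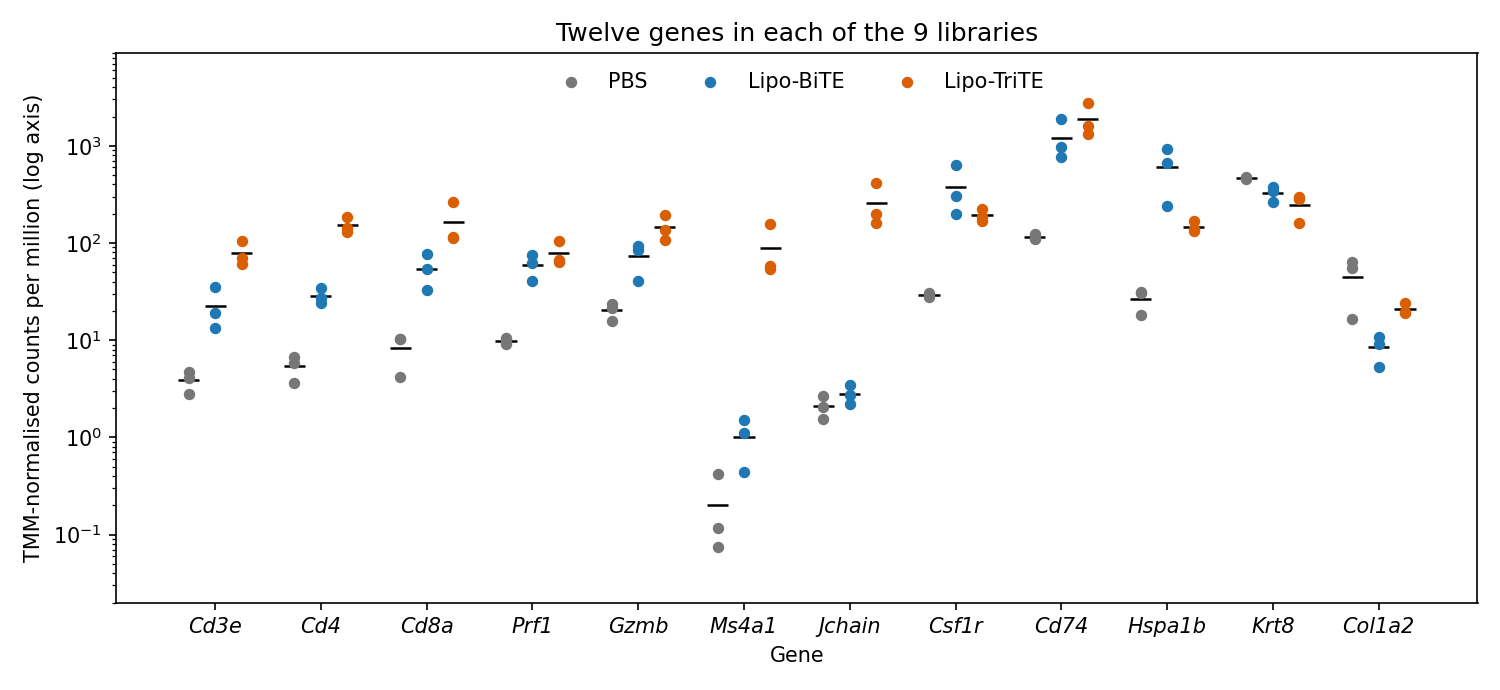
CPM after TMM scaling of 12 genes in each library, on a log axis, for PBS (grey), Lipo-BiTE (blue) and Lipo-TriTE (orange); points are libraries and bars are group means. Cd3e averaged 3.88, 22.6 and 78.8 CPM across the 3 groups, while Krt8 averaged 465, 329.1 and 246.5.

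Lipo-BiTE against PBS asked what differed after Lipo-BiTE. Both treatments carry the prefix Lipo, and the one control was PBS. No group given a carrier alone is among the samples, so an effect of any carrier cannot be told apart from that of the agent. Tumours given Lipo-BiTE carried more transcripts of T cells, natural killer (NK) cells, macrophages, neutrophils and dendritic cells than PBS tumours. With an estimated correlation only the dendritic list kept its call (adjusted p = 0.046), and the T cell, NK cell and macrophage lists (0.15 each) and the neutrophil list (0.25) lost theirs. Falls were partial: 9 of 18 fibroblast and matrix genes and 5 of 21 cell cycle genes fell, and both lists lost their calls with an estimated correlation (adjusted p = 0.15 and 0.29). All 22 T cell markers rose, with a median of 5.93-fold, and 11 of 12 neutrophil markers rose, with a median of 12.5-fold. Cd4, the helper T cell coreceptor, rose from 5.41 ± 1.57 to 28.7 ± 5.18 CPM, and Cd8a, the killer T cell coreceptor, from 8.3 ± 3.52 to 54.1 ± 21.8 CPM (SD, n = 3 each). Of 16596 genes tested, 2283 were higher and 534 lower at a Benjamini-Hochberg adjusted p under 0.05 in the edgeR quasi-likelihood test. In 42.1% of tested genes the 6 libraries did not overlap between groups, where chance gives 10%. Scaling by total counts alone moved the split to 2079 higher and 988 lower. The higher count dropped to 1455 without Lipo-BiTE 1. The lower count depended on single libraries, at 143, 199 and 176 without PBS 1, 2 and 3, and at 80, 104 and 971 without Lipo-BiTE 1, 2 and 3.

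T cell genes moved together. Cd3e rose 5.78-fold (log2 fold change 2.53, SE 0.38, edgeR quasi-likelihood adjusted p = 0.0015) and Trbc2, a constant region of the T cell receptor, 9.88-fold (adjusted p = 0.00076). All 9 NK cell genes rose, among them Ncr1, an activating receptor, at 4.46-fold (adjusted p = 0.001). Of 19 cytotoxicity genes 16 rose, 17 when adjusted over the list alone, with a median log2 change of 2.2. Prf1, the pore-forming protein perforin, rose 5.99-fold (adjusted p = 0.00076), Gzmb, a granule protease, 3.62-fold (adjusted p = 0.0032), and Ifng, the interferon made by activated T and NK cells, 5.28-fold (adjusted p = 0.0018). Activation genes rose in 17 of 19 cases (18 when adjusted over the list alone), with Tnf, which the inflammatory list also holds, at 9.67-fold. Exhaustion and checkpoint genes rose in 13 of 15 cases (14 when adjusted over the list alone). Members of both lists can also come from other cells of the mixture, so these rises do not show the state of T cells. Pdcd1, encoding PD-1, rose 6.63-fold (adjusted p = 0.0042; 11.4-fold without PBS 2) and Ctla4, a brake on costimulation, 8.08-fold (adjusted p = 0.0007). Each of these 5 lists rose in the camera test with a preset correlation (adjusted p of 6.1e-07 or below), and each lost that call at adjusted p = 0.15 with an estimated correlation.

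Regulatory, naive and helper T cell genes rose as well. In the regulatory list 10 of 13 genes rose, the same number when adjusted over the list alone, and the call held both ways (camera adjusted p = 3.2e-07, and adjusted p = 0.045 with an estimated correlation). Members of this list, too, can come from other cells of the mixture. Capg, at 432.9 to 463 CPM in PBS and 401.2 to 453.9 in Lipo-BiTE libraries, did not rise. The call thus does not show a rise of regulatory T cells alone. Foxp3, the lineage factor of regulatory T cells, rose from 2.05 ± 0.236 to 12.8 ± 1.63 CPM (SD, n = 3 each), or 6.22-fold (edgeR adjusted p = 0.0007). Naive and memory genes rose in 9 of 13 cases (11 when adjusted over the list alone; camera adjusted p = 1.7e-07, adjusted p = 0.15 with an estimated correlation), with Il7r, the interleukin 7 receptor, at 6.26-fold. Helper genes rose in 8 of 12 cases (8, and 1 fallen, when adjusted over the list alone; camera adjusted p = 0.0069, adjusted p = 0.25 with an estimated correlation), with the chemokine receptor Cxcr3 at 7.87-fold.

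Macrophage, neutrophil and MHC class II genes were among the strongest groups. The dendritic cell median, at log2 1.65, lay below the T cell median of 2.57. Of 16 macrophage and monocyte genes 15 rose, and Csf1r, the growth factor receptor of that lineage, went from 29.1 to 379 CPM (13-fold, edgeR adjusted p = 0.00076; 8.59-fold without Lipo-BiTE 1). All 12 neutrophil genes rose when adjusted over the list alone, against 11 over all genes; Csf3r, the receptor for granulocyte growth factor, rose 17.8-fold (10.7-fold without Lipo-BiTE 1) and Cxcl2, a neutrophil-attracting chemokine, 20.9-fold. Dendritic cell genes rose in 9 of 12 cases over either set, with Xcr1 of cross-presenting dendritic cells at 4.08-fold. All 11 genes of MHC class II presentation rose, with a median of 8.37-fold; Cd74, the class II invariant chain, went from 115 to 1200 CPM. Camera gave adjusted p = 1.1e-10 for macrophages, 6.1e-07 for neutrophils, 7.6e-07 for dendritic cells and 5.5e-10 for MHC class II. With an estimated correlation the dendritic list kept its call (adjusted p = 0.046 with an estimated correlation), while macrophages and MHC class II (adjusted p = 0.15 each) and neutrophils (adjusted p = 0.25) lost theirs.

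Inflammatory and interferon genes were also higher. Inflammatory cytokines and chemokines rose in 14 of 20 cases (16 when adjusted over the list alone), including Ccl4 at 13.6-fold and Nlrp3, an inflammasome sensor, at 13.2-fold. Genes of suppressive myeloid cells rose in 10 of 15 cases over either set, with the lipid receptor Trem2 at 12.1-fold. The interferon gamma response rose in 12 of 16 cases (14 when adjusted over the list alone), with Cxcl10, a T cell-attracting chemokine, at 4.26-fold. Cd274, which encodes the PD-1 ligand, went from 34.4 ± 5.92 to 357 ± 213 CPM (SD, n = 3 each; 10.4-fold, edgeR adjusted p = 0.0012). Type I interferon genes rose in 10 of 21 cases (13 when adjusted over the list alone), with the antiviral protein Mx1 at 7.96-fold. Camera called the inflammatory (adjusted p = 8.7e-09), suppressive (1.3e-05), interferon gamma (7.4e-07) and type I (0.00027) lists higher. With an estimated correlation these calls were lost, at adjusted p = 0.15, 0.15, 0.25 and 0.46 in that order.

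B cell genes rose in 3 of 14 cases over all genes and in 5 when adjusted over the list alone. These 3 were Ighm, the heavy chain of IgM, at 3.23-fold, and the B cell signalling proteins Bank1 at 8.56-fold (5.53-fold without Lipo-BiTE 1) and Cd22 at 12.4-fold (edgeR adjusted p = 0.00077, 0.0035 and 0.0071). The list was called higher by camera (adjusted p = 0.0011; adjusted p = 0.31 with an estimated correlation). The plasma cell list was not called (median log2 0.53, camera adjusted p = 0.12), though it was without PBS 1 (0.011).

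Part of the matrix and cell cycle genes fell. Of 18 fibroblast and matrix genes 9 fell, 11 when adjusted over the list alone, and 1 rose (camera adjusted p = 1.3e-05, adjusted p = 0.15 with an estimated correlation). Col1a2, a chain of type I collagen, dropped from 44.8 to 8.44 CPM (log2 −2.41, SE 0.45, edgeR adjusted p = 0.0045), and Postn, the matrix protein periostin, by log2 −2.18 (adjusted p = 0.0015). The riser was Thy1, which the T cell list also holds, at 5.91-fold. Cell cycle genes fell in 5 of 21 cases, 6 when adjusted over the list alone, with a median log2 change of −0.47 (camera adjusted p = 5.4e-06, adjusted p = 0.29 with an estimated correlation). Mcm6, a subunit of the replicative helicase, changed by log2 −0.74 (adjusted p = 0.0031). Erbb2 did not pass, at 19 ± 5.03 CPM against 21.3 ± 3.63 in PBS (SD, n = 3 each; log2 −0.17, edgeR adjusted p = 0.66), and its fold change was 0.04 on the log2 scale without Lipo-BiTE 1. Immediate early and heat shock genes, which tissue handling can move, rose in 10 of 13 cases (11 when adjusted over the list alone; camera adjusted p = 6.1e-07, adjusted p = 0.15 with an estimated correlation). Hspa1b, a heat shock chaperone, went from 26.7 to 605 CPM (22.6-fold, adjusted p = 0.00076).

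The largest single rises and falls stood partly outside these groups. Cldn1, a tight junction protein, rose 82.7-fold (edgeR adjusted p = 0.0017; 225-fold without PBS 2) and Lilra5, a receptor of myeloid cells, 62.9-fold (0.00079). Galnt6os, Erg, a transcription factor of endothelium, and Krt7, a keratin, had no counts in PBS and were at least 22.2-fold, 18.6-fold and 16.7-fold higher, with the bound set at 3 counts over the group. Galnt6os is an opposite-strand transcript and strand is not stated, so its reads may come from the other strand. The largest falls were of genes with 3 counts over the Lipo-BiTE libraries. Lum, encoding the matrix proteoglycan lumican, was lower by a ratio of 17.1 (exact 95% interval 5.58 to 85.2), Cyp24a1, a vitamin D hydroxylase, by 13.7 (4.43 to 68.9) and Gnaz, a G protein subunit, by 12.9 (4.14 to 64.8), with edgeR adjusted p = 0.036, 0.022 and 0.039. The fitted folds moved with single libraries, from 0.0614 to 0.00592 for Lum and from 0.077 to 0.0424 for Cyp24a1 without Lipo-BiTE 3, and from 0.0805 to 0.155 without PBS 1 or 0.043 without Lipo-BiTE 1 for Gnaz. Krt7 and these 3 genes lost their calls without a single library: Krt7 without any PBS library or Lipo-BiTE 1 (adjusted p from 0.053 to 0.0874), Lum without any PBS library, Lipo-BiTE 1 or 2 (0.0574 to 0.135), Cyp24a1 without PBS 1, PBS 3, Lipo-BiTE 1 or 2 (0.0561 to 0.0983) and Gnaz without any library but PBS 3 (0.0644 to 0.139). Of the genes named for this comparison that passed, 41 of 45 passed again whichever single library was left out.

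Lipo-TriTE against PBS asked the same question of the other agent. Tumours given Lipo-TriTE carried far more transcripts of T cells, B cells and antibody-producing cells than PBS tumours, along with more of NK, myeloid, dendritic and mast cells. Of these lists only the dendritic one kept its call with an estimated correlation (adjusted p = 0.022), and the T cell, B cell, plasma cell and NK cell lists (0.15 each) and the macrophage (0.18), neutrophil (0.27) and mast cell lists (0.19) lost theirs. All 22 T cell markers rose, with a median of 24.3-fold, and all 14 B cell markers, with a median of 156-fold. Cd3e rose from 3.88 ± 0.98 to 78.8 ± 23.7 CPM and Cd4 from 5.41 ± 1.57 to 153 ± 29.4 CPM (SD, n = 3 each). Lower were 7 of 18 fibroblast and matrix, 12 of 21 cell cycle and 10 of 19 TGF-beta genes, and these lists lost their calls with an estimated correlation (adjusted p = 0.18, 0.35 and 0.18). In all, 3133 genes were higher and 2449 lower of 16596 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and the libraries did not overlap in 49.5% of genes, where chance gives 10%. The lower count dropped to 1391 without PBS 2 and to 1440 without PBS 3.

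B cell and plasma cell genes showed the largest changes. Ms4a1, which encodes CD20, went from 0.203 to 89.2 CPM (409-fold, log2 8.67, SE 0.69, edgeR adjusted p = 3.3e-05; 843-fold without PBS 3 and 259-fold without Lipo-TriTE 1), and Fcer2a, the low-affinity IgE receptor, rose 309-fold (adjusted p = 1.9e-05). Ighm rose 49.6-fold, from 15.3 to 761 CPM. Of 11 plasma cell genes 10 rose; Jchain, which joins IgM and IgA chains, went from 2.1 to 259 CPM (124-fold, adjusted p = 9.9e-06) and Igkc, the kappa light chain constant region, from 8.75 to 1380 CPM (159-fold, or 93.6-fold without Lipo-TriTE 1). Ighe, the IgE constant gene, had no counts in PBS and was at least 168-fold higher. The exception was Txndc5, a protein folding enzyme picked out after its values were seen, which fell by 0.51 on the log2 scale (adjusted p = 0.0226), but not without PBS 2 (0.0939), PBS 3 (0.0594), Lipo-TriTE 2 (0.0595) or Lipo-TriTE 3 (0.0674). Counts over all genes and adjusted over the list alone were the same for both lists. Camera gave adjusted p = 3.1e-12 for B cells and 1.5e-06 for plasma cells, with adjusted p = 0.15 for each with an estimated correlation.

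T cell genes rose across subsets. Trbc2 rose 54.4-fold (edgeR adjusted p = 5.6e-06), Cd8a 19.6-fold (0.00018) and Foxp3 13.2-fold (5.6e-06). Naive and memory genes rose in 12 of 13 cases, with a median of 23.6-fold; S1pr1, the receptor that lets lymphocytes leave tissue, rose 43.1-fold (3.3e-06) and Lef1, a transcription factor of naive T cells, 32.9-fold (5.6e-06). Cytotoxicity genes rose in 18 of 19 cases (19 when adjusted over the list alone), with Prf1 at 7.98-fold, Gzmb at 7.16-fold and Ifng at 6.61-fold (adjusted p = 4e-05, 0.00021 and 0.00052). Activation genes rose in 17 of 19 cases, and Cd27, a costimulatory receptor, rose 37.4-fold. Checkpoint genes rose in 14 of 15 cases, with Btla, an inhibitory receptor of lymphocytes, at 49.1-fold and Pdcd1 at 11.3-fold (19.8-fold without PBS 2). S1pr1 and Btla are genes of lymphocytes in general, and B cell markers rose in the same libraries. B cells or other cells of the mixture may thus hold part of the naive, activation and checkpoint rises. Helper genes rose in 9 of 12 cases, regulatory genes in 12 of 13 and NK cell genes in 9 of 9, with Ncr1 at 7.21-fold. For activation, checkpoint, helper, regulatory, naive and NK lists the counts risen were the same when adjusted over the list alone. Nr4a2, an immediate early factor picked out after its values were seen, was the member that fell in both the activation and checkpoint lists (log2 −0.94, adjusted p = 0.0119), though not without PBS 3 (0.059) or Lipo-TriTE 2 (0.0504).

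Camera placed these lists above the other genes, from adjusted p = 1.5e-18 for T cells and 8.6e-10 for naive genes to 6.6e-05 for helper genes. Members of the regulatory list can also come from other cells of the mixture. That list kept its call with an estimated correlation (adjusted p = 4e-08, and adjusted p = 0.022 with an estimated correlation). The T cell, naive, activation and NK lists lost theirs (adjusted p = 0.15 each with an estimated correlation), as did the cytotoxicity, checkpoint and helper lists (adjusted p = 0.17 each).

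Dendritic cell genes rose in 11 of 12 cases over either set, and both list tests called them (camera adjusted p = 1.5e-08, adjusted p = 0.022 with an estimated correlation). Flt3, the growth factor receptor of dendritic cell precursors, rose 11.4-fold (edgeR adjusted p = 5.7e-06) and Siglech, a marker of plasmacytoid dendritic cells, 14.6-fold (2.6e-05). Fscn1, an actin-bundling protein picked out after its values were seen, was the 1 that fell (log2 −0.79, adjusted p = 0.0161), though not without PBS 2 (0.0748), PBS 3 (0.0587) or Lipo-TriTE 3 (0.0522). MHC class II genes rose in 11 of 11 cases over either set, with a median of 16.4-fold and H2-Aa at 17.3-fold. Genes of lymphoid tissue chemokines and their receptors rose in 7 of 7 cases over either set, including Ccr7, the homing receptor for lymph nodes, at 28.1-fold and Ltb, encoding lymphotoxin beta, at 32.2-fold. Camera gave adjusted p = 3.3e-09 for MHC class II and 2.4e-06 for the lymphoid list, against adjusted p = 0.17 and 0.15 with an estimated correlation.

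Macrophage and monocyte genes rose in 15 of 16 cases, with Ccr2, a chemokine receptor of monocytes, at 8.97-fold. Mertk, a receptor for the uptake of dying cells that was picked out after its values were seen, fell (log2 −0.89, edgeR adjusted p = 0.007). All 12 neutrophil genes rose, with the granule protein gene Camp at 16.2-fold, and mast cell and eosinophil genes rose in 7 of 8 cases, with the mast cell protease gene Tpsb2 at 7.32-fold. Inflammatory genes rose in 14 of 20 cases and fell in 2, with Il1b, encoding interleukin 1 beta, at 11.6-fold. For these 4 lists the counts were the same when adjusted over the list alone. Camera gave adjusted p = 4.5e-07, 4.7e-06, 0.00057 and 0.0022 in that order, and the calls were lost at adjusted p = 0.18, 0.27, 0.19 and 0.38 with an estimated correlation. Cd274 rose 4.78-fold, to 165 ± 42.5 CPM (SD, n = 3; adjusted p = 0.0043). The interferon gamma list rose in 13 of 16 cases (14 when adjusted over the list alone; camera adjusted p = 3.4e-05, adjusted p = 0.34 with an estimated correlation).

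Erbb2 and part of the matrix and cell cycle genes moved the other way. The epithelial tumour cell list was not called: 4 of 12 genes rose and 3 fell, or 4 and 4 when adjusted over the list alone (camera adjusted p = 0.84). Erbb2 fell from 21.3 ± 3.63 to 8.72 ± 0.883 CPM (SD, n = 3 each; log2 −1.28, SE 0.24, edgeR adjusted p = 0.0024). Whether its counts include the added HER2 is not known. Krt8, chosen after its values were seen, fell from 465 to 246.5 CPM (log2 −0.92, adjusted p = 0.0098). TGF-beta and mesenchymal genes fell in 10 of 19 cases (11 when adjusted over the list alone), with the matrix protein gene Tnc at log2 −1.48 (adjusted p = 0.00022), while 2 rose. Fibroblast and matrix genes fell in 7 of 18 cases (9 when adjusted over the list alone), with Fn1, encoding fibronectin, at log2 −1.08. Cell cycle genes fell in 12 of 21 cases, and in 16 when adjusted over the list alone, with Rrm2, a subunit of ribonucleotide reductase, at log2 −0.94 (adjusted p = 0.0064). Camera called all 3 lists lower (adjusted p = 0.00039, 0.0025 and 2.1e-05), and adjusted p was 0.18, 0.18 and 0.35 with an estimated correlation. Immediate early and heat shock genes rose in 6 of 13 cases (7 when adjusted over the list alone), with Hspa1b at 5.48-fold. That list's call (camera adjusted p = 0.043, adjusted p = 0.48 with an estimated correlation) ended without PBS 1 (adjusted p = 0.14), Lipo-TriTE 1 (0.095) or Lipo-TriTE 2 (0.062). Of the genes named for this comparison that passed, 41 of 44 passed again whichever single library was left out.

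**Figure D3:**
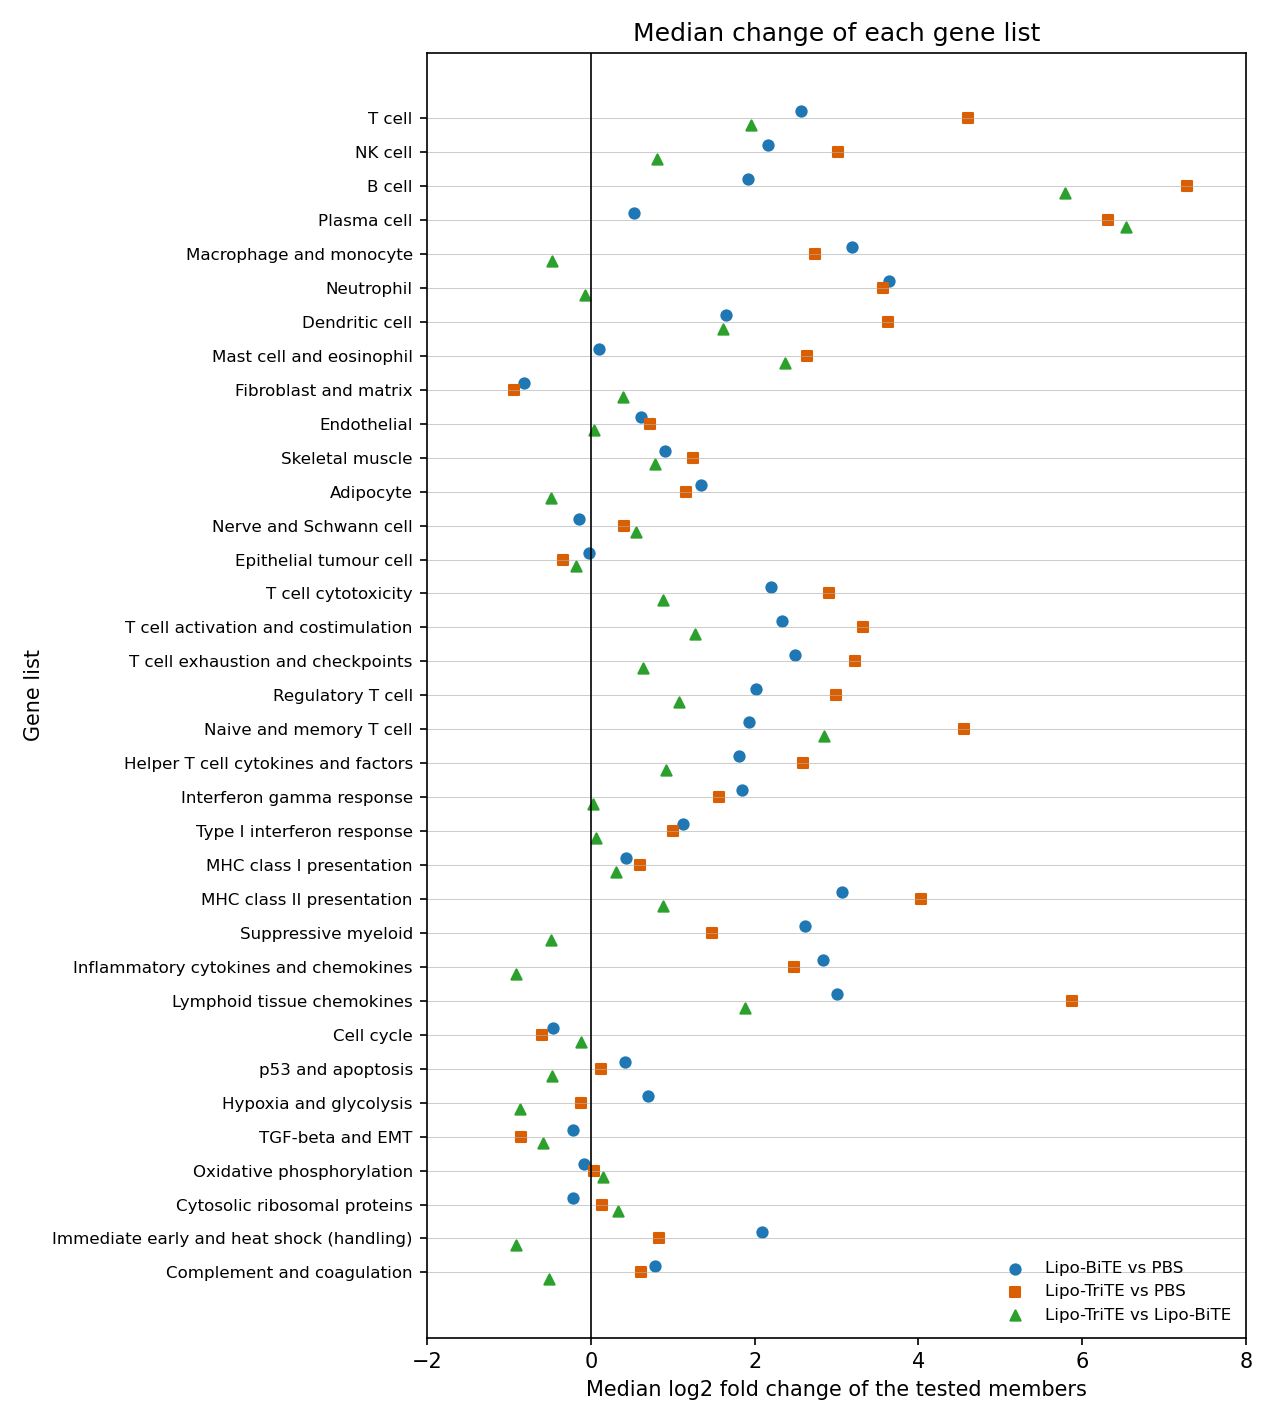
Median log2 fold change of the tested members of each gene list for Lipo-BiTE against PBS (circles), Lipo-TriTE against PBS (squares) and Lipo-TriTE against Lipo-BiTE (triangles). B cell and plasma cell lists reach 7.28 and 6.32 in Lipo-TriTE against PBS, against 1.92 and 0.53 in Lipo-BiTE against PBS.

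The changes against PBS overlapped between the agents. An effect of any carrier common to both cannot be told apart from theirs, as the one control was PBS. Genes higher in both numbered 1883, where independent lists of these sizes would share 431, and genes lower in both 359, against 78.8. Calls went in opposite directions for 10 genes. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.676. It was 0.499 for simulated unchanged groups that shared simulated PBS libraries. Covariance was 1.36, beside 0.147 in the simulations, a difference of 1.213. Simulated groups shared 0 calls in either direction. Groups without change yield almost no calls, so this followed from the setting and does not measure what shared controls add. The 3 PBS libraries cannot be split into parts of at least 2, so part of the excess of shared calls over independent lists may come from the shared controls.

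Lipo-TriTE against Lipo-BiTE tested the difference between the agents directly. Tumours given Lipo-TriTE held more B cell, plasma cell, T cell and dendritic cell transcripts than those given Lipo-BiTE. None of the 35 lists was called with an estimated correlation, with adjusted p = 0.097 for B cells and for plasma cells, 0.2 for T cells and 0.054 for dendritic cells. Lower were 8 of 16 hypoxia, 8 of 19 TGF-beta and 4 of 13 immediate early genes, in lists whose calls were lost the same way (adjusted p = 0.28, 0.2 and 0.26). Fry, which tests a list on its own, called 16 of the 35 lists. It gave adjusted p = 0.00018 for B cells and for plasma cells, 0.003 for T cells and 7.2e-05 for dendritic cells. Of the lists camera called, fry did not call cytotoxicity (adjusted p = 0.072), MHC class II (0.084) or ribosomal proteins (0.11). Nor did it call the checkpoint, MHC class I and inflammatory lists (0.21 each). All 14 B cell genes rose, with a median of 55.2-fold, and 9 of 11 plasma cell genes, with a median of 92.8-fold. Of 22 T cell genes 20 rose, with a median of 3.89-fold, and 22 when adjusted over the list alone. The macrophage list was not called (median log2 −0.48, camera adjusted p = 0.18), but was lower without Lipo-BiTE 2 (0.0077) or Lipo-BiTE 3 (0.025). The edgeR quasi-likelihood test called 810 genes higher and 865 lower (Benjamini-Hochberg adjusted p under 0.05), or 1099 and 451 with scaling by total counts alone; libraries did not overlap in 30.5% of genes, where chance gives 10%. Higher calls dropped to 276, 476 and 479 without Lipo-BiTE 2, Lipo-BiTE 3 and Lipo-TriTE 3. Lower calls dropped to 158 and 556 without Lipo-BiTE 2 and 3, and to 524, 418 and 293 without Lipo-TriTE 1, 2 and 3.

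Antibody and B cell genes led. Ighg2b, the IgG2b constant gene, rose from 0.974 to 645 CPM (653-fold, log2 9.35, SE 0.87, edgeR adjusted p = 0.00047), Jchain 92.8-fold (8.1e-05), Ms4a1 87.7-fold (0.00041) and Ighm 15.4-fold (4.7e-05). Cr2, the complement receptor of B cells and follicular dendritic cells, rose 65.2-fold (0.0011). Without Lipo-TriTE 1 the folds were 258-fold for Ighg2b, 56-fold for Ms4a1 and 41.7-fold for Cr2. Counts for both lists were the same when adjusted over the list alone. Camera gave adjusted p = 6.4e-18 for B cells and 3.5e-09 for plasma cells, and adjusted p = 0.097 for each with an estimated correlation. Reads of immunoglobulin, granzyme and MHC genes can be split between close relatives, and strand is not stated, so values of single family members are uncertain.

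Among T cell genes the median change was 7.17-fold for naive and memory genes and 1.84-fold for cytotoxicity genes. Some members, such as S1pr1, are genes of lymphocytes in general, so B cells may hold part of these rises. Cd4 rose 5.33-fold, from 28.7 ± 5.18 to 153 ± 29.4 CPM (SD, n = 3 each; edgeR adjusted p = 0.00041). Cd3e rose 3.49-fold (adjusted p = 0.013), but at adjusted p = 0.0689 without Lipo-BiTE 2. Cd8a rose 3.02-fold (adjusted p = 0.043), with adjusted p = 0.137, 0.0846, 0.121 and 0.0644 without Lipo-BiTE 2, Lipo-BiTE 3, Lipo-TriTE 1 and Lipo-TriTE 3. Naive and memory genes rose in 10 of 13 cases (11, and 1 fallen, when adjusted over the list alone), with S1pr1 at 11-fold (8.1e-05) and Lef1 at 8.64-fold (0.00015). Activation genes rose in 11 of 19 cases (13, and 4 fallen, when adjusted over the list alone), with the costimulatory genes Cd40lg at 7.07-fold and Icos at 3.76-fold. Cytotoxicity genes rose in 5 of 19 cases (9 when adjusted over the list alone), with Gzma, a granule protease, at 4.1-fold (0.0021). Prf1 did not pass, at 1.33-fold (0.31), nor did Gzmb at 1.98-fold (0.072) or Ifng at 1.25-fold (0.62), and Ifng stood at log2 −0.02 without Lipo-TriTE 1.

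Helper genes rose in 4 of 12 cases (5 when adjusted over the list alone; camera adjusted p = 0.0021, adjusted p = 0.26 with an estimated correlation). NK cell genes rose in 3 of 9 cases over either set (camera adjusted p = 0.00028, adjusted p = 0.26 with an estimated correlation). Regulatory genes rose in 5 of 13 cases (9 when adjusted over the list alone), with Foxp3 at 2.12-fold (edgeR adjusted p = 0.0084, or 0.0566 without Lipo-BiTE 2). Checkpoint genes rose in 3 of 15 cases over either set, and Pdcd1 did not pass at 1.7-fold (adjusted p = 0.32). The checkpoint list's call (camera adjusted p = 0.027) ended without Lipo-BiTE 3 (0.33) or Lipo-TriTE 1 (0.14). Camera gave adjusted p = 3.4e-17 for T cells, 3.1e-09 for naive, 2.9e-05 for regulatory, 6.6e-05 for cytotoxicity and 0.00022 for activation genes. With an estimated correlation these became adjusted p = 0.2, 0.2, 0.054, 0.42 and 0.34, and 0.57 for checkpoints.

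Dendritic cell genes rose in 8 of 12 cases (9, and 1 fallen, when adjusted over the list alone; camera adjusted p = 2.3e-07, adjusted p = 0.054 with an estimated correlation), with Siglech at 12.2-fold (edgeR adjusted p = 0.00016) and Flt3 at 5.76-fold (0.00014). Mast cell and eosinophil genes rose in 5 of 8 cases (6 when adjusted over the list alone; camera adjusted p = 4.9e-05, adjusted p = 0.22 with an estimated correlation), with Tpsb2 at 4.73-fold. Lymphoid tissue chemokines rose in 4 of 7 cases (6 when adjusted over the list alone; camera adjusted p = 5.3e-05, adjusted p = 0.2 with an estimated correlation). MHC class II genes rose in 4 of 11 cases (5 when adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.48 with an estimated correlation), with H2-Ob, a class II regulator of B cells, at 14.8-fold.

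Hypoxia and glycolysis genes fell in 8 of 16 cases (13 when adjusted over the list alone), with Car9, a carbonic anhydrase induced by low oxygen, at log2 −1.65 (edgeR adjusted p = 0.0043). TGF-beta and mesenchymal genes fell in 8 of 19 cases over either set, with Snai1, a repressor of epithelial genes, at log2 −1.48 (0.0073). Immediate early and heat shock genes fell in 4 of 13 cases and in 10 when adjusted over the list alone. Hspa1b fell (log2 −2.05, adjusted p = 0.014) but not without Lipo-BiTE 2, Lipo-TriTE 1 or Lipo-TriTE 3 (0.0542, 0.0536 and 0.0584). Camera called these lists lower (adjusted p = 1.4e-06, 1.2e-05 and 3.9e-05), and adjusted p was 0.28, 0.2 and 0.26 with an estimated correlation. Erbb2 was lower (log2 −1.12, adjusted p = 0.018), with adjusted p = 0.0807 and 0.0571 without Lipo-BiTE 2 and 3, and 0.0531 and 0.0618 without Lipo-TriTE 2 and 3. Cd274 did not pass (log2 −1.12, adjusted p = 0.14), but did without Lipo-BiTE 3 (log2 −1.51, adjusted p = 0.00508). Of the genes named for this comparison that passed, 18 of 25 passed again whichever single library was left out.

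In the C57BL/6NJ gene models as the count table gives them, Cd3e lies on chromosome 9 at 44815479 to 44826326 (minus strand), Cd4 on chromosome 6 at 131555640 to 131579161 (minus) and Cd8a on chromosome 6 at 73740391 to 73745169 (plus). Prf1 lies on chromosome 10 at 62786830 to 62794028 (plus), Gzmb on chromosome 14 at 52857646 to 52861050 (minus) and Ifng on chromosome 10 at 125584926 to 125589771 (plus). Foxp3 spans 2268170 to 2285428 of chromosome X (plus), Pdcd1 99454897 to 99469089 of chromosome 1 (minus), Cd274 28595293 to 28617586 of chromosome 19 (plus) and Erbb2 104040134 to 104071323 of chromosome 11 (plus). Counts cover the whole gene, so exons are not told apart.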

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

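The alternatives without unnamed loci, with thinned libraries and with 2 libraries per group were chosen only after the data were seen; all others were planned. Direction and call held in 1966 of the 2033 values that alternatives gave for the 120 named gene results, while 56 lost a call, 6 gained one and 5 reversed. Counts of calls stayed within 1.5 times of the reported ones except as follows, and the cause was not tested where none is given.

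For Lipo-BiTE against PBS, limma voom called 4656 genes higher and 4313 lower. The lower count was 988 with total counts, 839 with no filter, 995 with the DESeq2 Wald test, 282 with the replicate block, 1259 with 2 libraries per group and 135 with the added fold threshold, which by construction removes smaller changes. For Lipo-TriTE against PBS, voom called 3755 lower and the fold threshold left 832 lower. For Lipo-TriTE against Lipo-BiTE, the higher count was 1538 with no filter, 1475 with the DESeq2 Wald test and 2944 with voom. Its lower count was 451 with total counts, 1455 with no filter, 510 with only the 2 groups compared, 2726 with voom, 1401 with 2 libraries per group and 344 with the fold threshold. Keeping 2 libraries per group left out PBS 1, Lipo-BiTE 3 and Lipo-TriTE 1, the library least correlated with its group, which narrows the spread by construction.

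With an estimated correlation 2, 2 and 0 lists were called in the 3 comparisons, and the reason for the loss of calls was not tested. The correlation of the changes against PBS was 0.478 with no filter and 0.841 with only the 2 groups compared. Leaving out 1 library gave 1455 to 2656 genes higher and 80 to 971 lower for Lipo-BiTE against PBS, 2575 to 2925 and 1391 to 2222 for Lipo-TriTE against PBS, and 276 to 901 and 158 to 1031 for Lipo-TriTE against Lipo-BiTE. Lists called ranged over 23 to 28, 23 to 25 and 19 to 25, and the correlation over 0.576 to 0.682. With fewer libraries the spread is less well known, so part of the losses follows from the smaller number.

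The following values reversed. The log2 change of Erbb2, Lipo-BiTE vs PBS, not called, ranged from −0.305 without PBS 1 to 0.042 without Lipo-BiTE 1. In Lipo-TriTE against Lipo-BiTE, Prf1, not called, was −0.018 with 2 libraries per group. Ifng, not called, was −0.197 with voom and −0.231 with 2 libraries per group, and ranged from −0.018 without Lipo-TriTE 1 to 0.65 without Lipo-TriTE 2. The nerve and Schwann cell score was −0.56 as a median of its genes in place of a mean.

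Replicate numbers are shared across groups, but no label ties them to an animal or day. None of the 9 same-numbered pairs correlated above 0.1 in their deviations from the group means (−0.19 to 0.076), and 2 libraries correlated best with their own number. The replicate block called 1892 genes higher and 282 lower, 2846 and 2074, and 649 and 604 in the 3 comparisons. Depth limits low genes: 3 counts equal 0.148 to 0.228 CPM, and thinning to the smallest library gave 2238 and 514, 3187 and 2228, and 845 and 730 calls.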

Other observations

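The tests of the 3 patterns weighed here, and the receptor sums, were chosen only after the results were seen; the counts of other splits were planned. Receptor gene segments followed the marker lists. Constant genes of immunoglobulins summed to 33 to 58.2 CPM in PBS, 74.9 to 85.9 in Lipo-BiTE and 2987 to 10533 in Lipo-TriTE libraries, and variable segments to 3.28 to 4.26, 3.07 to 6.3 and 206 to 796 CPM. Variable segments of the T cell receptor summed to 2.28 to 3.59, 8.25 to 17.6 and 55.3 to 90.7 CPM. Of 175 immunoglobulin variable genes, 1 to 2 had at least 10 counts in a PBS library, 1 in a Lipo-BiTE library and 50 to 77 in a Lipo-TriTE library; of 90 T cell receptor variable genes the numbers were 0 to 1, 3 to 9 and 21 to 29. Segments are close relatives, so single segments are not named. Xist, a transcript of female cells, and Ptprc, which encodes the leukocyte protein CD45, were chosen after their values were seen. Xist averaged 22.96 CPM in PBS, 245.1 in Lipo-BiTE and 404.9 in Lipo-TriTE, and Ptprc 88.58, 942 and 1456 CPM (edgeR adjusted p for Xist 0.000765 and 3.35e-05 against PBS).

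In Lipo-TriTE against PBS 7 of 14 genes of antigen presentation through MHC class I rose over either set, with the immunoproteasome activator gene Psme2 at 1.82-fold (edgeR adjusted p = 0.001; camera adjusted p = 0.0026, adjusted p = 0.41 with an estimated correlation). With 1 of 14 genes risen, and 0 when adjusted over the list alone, the class I list was called higher in Lipo-BiTE against PBS (camera adjusted p = 0.047, adjusted p = 0.55 with an estimated correlation), but not without PBS 2 (0.09), PBS 3 (0.12), Lipo-BiTE 1 (0.077) or Lipo-BiTE 2 (0.12), and, with 1 of 14 risen over either set, in Lipo-TriTE against Lipo-BiTE (0.029, adjusted p = 0.57 with an estimated correlation), but not without Lipo-BiTE 1 (0.075), Lipo-BiTE 3 (0.16) or Lipo-TriTE 1 (0.45). Type I interferon genes rose in 10 of 21 cases in Lipo-TriTE against PBS (11 when adjusted over the list alone; camera adjusted p = 0.0044, adjusted p = 0.58 with an estimated correlation), with the RNA-sensing enzyme gene Oas2 at 6.74-fold, and the call ended without Lipo-TriTE 1 (0.091). Suppressive myeloid genes rose in 8 of 15 cases and fell in 2 in Lipo-TriTE against PBS (9 and 2 when adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.38 with an estimated correlation), a call that ended without Lipo-TriTE 2 (0.062) or Lipo-TriTE 3 (0.053). In Lipo-TriTE against Lipo-BiTE 3 of 15 fell and 0 rose, and the list was not called (camera adjusted p = 0.053). It was called lower without Lipo-BiTE 2 (0.034), Lipo-BiTE 3 (0.012), Lipo-TriTE 2 (0.024) or Lipo-TriTE 3 (0.033). The inflammatory list was called lower in Lipo-TriTE than in Lipo-BiTE, with 3 of 20 genes fallen, 1 risen and 16 not passed, and the same 3 and 1 when adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.57 with an estimated correlation), though not without Lipo-BiTE 1 (0.083) or Lipo-TriTE 1 (0.14); Ccl2, a monocyte-attracting chemokine, stood at log2 −1.13 (edgeR adjusted p = 0.0086). The riser was Il12b, a subunit of interleukin 12, at 3.22-fold (0.025), though not without Lipo-BiTE 1, 2 or 3 or Lipo-TriTE 2 or 3 (0.0517 to 0.105). Lymphoid tissue chemokines rose in 5 of 7 cases in Lipo-BiTE against PBS (7 when adjusted over the list alone; camera adjusted p = 2.9e-05, adjusted p = 0.15 with an estimated correlation).

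Hypoxia and glycolysis genes rose in 8 of 16 cases in Lipo-BiTE against PBS (10 when adjusted over the list alone; camera adjusted p = 5.9e-05, adjusted p = 0.29 with an estimated correlation), with Pfkfb3, a regulator of glycolysis, at 6.53-fold (edgeR adjusted p = 0.0022). Against PBS the Lipo-TriTE list was not called, and its median, −0.12, and mean, 0.19, differed in sign (camera adjusted p = 0.62). The p53 and apoptosis list was called lower in Lipo-TriTE than in Lipo-BiTE, with 4 of 18 genes fallen, 1 risen and 13 not passed, or 6 and 1 when adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.26 with an estimated correlation), but not without Lipo-BiTE 1 (0.073). The riser was the p53 target gene Trp53inp1, at 2.6-fold (edgeR adjusted p = 0.012), though not without Lipo-BiTE 2 (0.0591). In Lipo-BiTE against PBS the p53 list was not called (camera adjusted p = 0.086), but was higher without Lipo-BiTE 3 (0.041). In Lipo-TriTE against Lipo-BiTE the cell cycle list was not called (camera adjusted p = 0.49), but was lower without Lipo-BiTE 1 (0.027). The ribosomal protein list was called lower in Lipo-BiTE against PBS, though 0 of 20 genes fell over either set (median log2 −0.22, camera adjusted p = 0.024, adjusted p = 0.54 with an estimated correlation), but not without PBS 1 (0.27) or Lipo-BiTE 2 (0.12), and higher in Lipo-TriTE against Lipo-BiTE, where 2 of 20 rose, or 3 when adjusted over the list alone (median 0.33, camera adjusted p = 0.0021, adjusted p = 0.54 with an estimated correlation). Oxidative phosphorylation genes had medians of −0.09, 0.03 and 0.15 in the 3 comparisons (camera adjusted p = 0.2, 0.67 and 0.054), and were called higher in Lipo-TriTE against Lipo-BiTE without Lipo-BiTE 3 (0.018). The complement and coagulation list was not called (camera adjusted p = 0.069, 0.45 and 0.18), but was higher in Lipo-BiTE against PBS without Lipo-BiTE 1 (0.028) or Lipo-BiTE 3 (0.043) and lower in Lipo-TriTE against Lipo-BiTE without Lipo-BiTE 3 (0.023); C3, the central complement protein, rose 11.3-fold in Lipo-BiTE against PBS (edgeR adjusted p = 0.0011).

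Camera seldom called the lists of other tissues, but fry called more of them. Fry called the skeletal muscle list in all 3 comparisons (adjusted p = 0.00094, 2.8e-05 and 0.0022). In both comparisons with PBS it called the endothelial (0.0022 and 0.007) and adipocyte lists (0.0074 and 0.007). It also called the nerve list in Lipo-TriTE against PBS (0.0091). The mean muscle score was 1.44 in PBS, 1.84 in Lipo-BiTE and 2.42 in Lipo-TriTE, without overlap between groups. The endothelial list was called higher in Lipo-BiTE against PBS, with 2 of 8 genes risen over either set (camera adjusted p = 0.047, adjusted p = 0.17 with an estimated correlation), but not without PBS 2 (0.12) or Lipo-BiTE 2 (0.06). The adipocyte list was called higher in Lipo-BiTE against PBS, with 3 of 5 genes risen over either set (camera adjusted p = 0.016, adjusted p = 0.19 with an estimated correlation) and in Lipo-TriTE against PBS, with 2 of 5 (0.041, adjusted p = 0.26 with an estimated correlation), the latter not without PBS 1, 2 or 3 (0.088, 0.12 and 0.12) or Lipo-TriTE 1, 2 or 3 (0.13, 0.17 and 0.15). Skeletal muscle (camera adjusted p = 0.17, 0.059 and 0.083), nerve and Schwann cell (0.62, 0.5 and 0.41) and epithelial tumour cell lists (0.82, 0.84 and 0.66) were called by camera in none of the 3 comparisons with all libraries. In the epithelial list the median was −0.02 and the mean 0.75 in Lipo-BiTE against PBS, and −0.34 and 0.74 in Lipo-TriTE against PBS, and the nerve list had a median of −0.15 and a mean of 0.91 in the former. Median, mean or test differed in sign, with no call over all libraries, in 5 further cases. They were TGF-beta genes in Lipo-BiTE against PBS (−0.22 and 0.05, camera adjusted p = 0.44) and, in Lipo-TriTE against Lipo-BiTE, neutrophil (−0.08 and 0.18, 0.46), interferon gamma (0.02 and −0.15, 0.83) and type I interferon genes (0.06 and −0.06, 0.8). The fifth, endothelial genes, had a median of 0.04 and a mean of 0.06 with a test pointing lower (0.75). Interferon gamma genes were called lower without Lipo-BiTE 3 (0.023), and type I genes without Lipo-BiTE 3 (0.0063) or Lipo-TriTE 1 (0.02). With total counts the neutrophil median became 0.1, that of mast cells in Lipo-BiTE against PBS went from 0.1 to −0.01, and that of cell cycle genes in Lipo-TriTE against Lipo-BiTE from −0.12 to 0. Skin epithelium had 3 tested genes and erythroid cells 2, too few for a list test, with median log2 changes of −0.74 and 1.34 in Lipo-BiTE against PBS and −0.43 and 0.71 in Lipo-TriTE against PBS. In Lipo-TriTE against Lipo-BiTE these medians were −0.12 and −0.63, and the skin epithelium mean, 0.54, differed in sign from its median. The mitochondrially encoded list had 0 tested genes; an assembled locus whose annotation names a mitochondrial oxidase subunit held 1628 to 4471 CPM in PBS, 1945 to 6578 in Lipo-BiTE and 2808 to 7888 in Lipo-TriTE libraries.

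Keratin transcripts were found in every library although the design text speaks of sorted T cells. Sorted T cells alone would hold far less Krt8 than Cd3e, but the lowest ratio of their CPM over 9 libraries was 1.5, which argues against libraries of T cells alone. Tumour cells carried over in a sort could still account for part of it and cannot be told apart from whole tissue here, since the ratio reached 164 and no measure of sort purity is among the values. A library of whole tumour tissue, as the labels say, would be consistent with both values, and this stays a hypothesis.

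B cell and plasma cell transcripts were far higher in Lipo-TriTE than in Lipo-BiTE libraries. A rise of all leukocytes by one factor is argued against: the B cell score less the macrophage score differed by 5.45 on the log2 scale between the treated groups, with a pooled SD of 0.814 (exact permutation p = 0.1, the smallest possible). Blood as the source cannot be told apart: the 5 of 9 listed erythroid genes that were measured summed to a mean of 2.8 CPM in Lipo-TriTE against 12.5 in Lipo-BiTE, a difference of −9.7 with a pooled SD of 9.65 (exact permutation p = 0.4), and Lipo-BiTE 1 alone held 27.8. Lymphoid tissue in the Lipo-TriTE samples, such as a piece of lymph node, may contribute and cannot be told apart from B cells within the tumour: Glycam1, Madcam1 and Cxcl13 together held 6, 14 and 16 counts in Lipo-TriTE 1, 2 and 3, against at most 5 in Lipo-BiTE and 4 in PBS libraries. Lipo-TriTE 1, with the highest B cell score of the 3 (7.22 against 5.93 and 5.95), held the fewest. These counts are near the floor and the level a given amount of node would bring is unknown, so they do not decide. The lymphoid tissue chemokine score was highest in Lipo-TriTE 1 (4.81 against 4.23 and 4.28), as was the naive and memory score (6.8 against 6.18 and 6.06). Lymphocytes within the tumour hold such transcripts too, so these scores do not decide either. B cells drawn in by the treatment remain an untested candidate explanation.

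Cytotoxicity genes lagged behind T cell genes in both treated groups, most in Lipo-TriTE. The cytotoxicity score less the T cell score averaged −0.03 in PBS, −0.709 in Lipo-BiTE and −1.86 in Lipo-TriTE. Between Lipo-TriTE and Lipo-BiTE it differed by −1.15 (pooled SD 0.187, exact permutation p = 0.1, the smallest possible). T cells of one makeup, only more numerous, would move both scores alike if all cytotoxicity transcripts came from T cells. The values argue against both conditions holding together. They do not decide on T cell makeup alone, since the source of the transcripts is not known. Part of the cytotoxicity transcripts may come from cells other than T cells, which cannot be told apart here: the NK cell score differed by 0.98, and no transcripts per cell type were measured. Of the 9 tested NK cell genes 3 stand in other lists too, and Klrk1 and Gzma are in the cytotoxicity list itself. The NK cell score is thus not independent of the cytotoxicity score. A larger share of naive or helper T cells after Lipo-TriTE could also give this and was not tested.

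Among 10 splits of the 6 libraries in each comparison, 1 split, the real one, gave as many called genes, at 2817, 5582 and 1675 for Lipo-BiTE against PBS, Lipo-TriTE against PBS and Lipo-TriTE against Lipo-BiTE, and the highest other split gave 0 each time. Each other split mixed libraries of both compared treatments in its groups, so the treatment difference entered the estimated spread. Few or no gene calls there followed from this setting, so the gene counts do not measure support for the real grouping. For lists, 1 of 10 splits gave as many calls, with 26, 26 and 21 for the real split and 25, 23 and 20 for the highest other. The highest other split thus gave nearly as many list calls as the real one, so the number of such calls says little about the grouping. With 10 splits no share under 0.05 can be reached.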
